A study of Glycine max with 16 samples.

How the data were processed

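RNA-seq was done on whole leaf tissue of soybean (Glycine max), taken from the 3 leaflets of leaf 5 (counted as trifoliate leaves), in plants held in CSTR exposure chambers at 25 or 75 ppb ozone. The 16 libraries cross a line letter (F or M) with the ozone level and 4 time points, 30 minutes apart and starting 5 hours after ozone was introduced. Per the labels, replicates were pooled at RNA extraction, so each combination of line, ozone level and time has 1 library. Libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The letters are not spelled out in the labels. The study as published compared the ozone-tolerant cultivar Fiskeby III with the ozone-sensitive Mandarin (Ottawa), and the text below keeps to the letters.

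The deposited files list transcripts with FPKM (fragments scaled to transcript length and to the mapped fragments of the library), held together with other values as text in the attribute column of each file. TopHat2 2.0.9 and Cufflinks 2.1.1 were used, per the submitters' processing notes. Per the file contents, Cufflinks wrote both annotated transcripts and newly assembled ones, and the identifiers are those of the Wm82.a2.v1 annotation. Coordinates below are the ones in these files. Read length, trimming, alignment options, strand use and the treatment of reads that map to several places are not given in the sources used here. Soybean holds many duplicated genes, and Cufflinks divides such reads by a model, so values of near-identical copies and of overlapping genes are uncertain.

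From these values a gene's FPKM was computed as the sum over its annotated transcripts and over new transcripts of the same Cufflinks locus, the latter given to the gene with the largest exonic overlap. The ratio of coverage to FPKM was constant within each deposited file and served as a measure of relative depth. It lay between 5.10 and 8.18 in all libraries except the one labelled M at 75 ppb, time point 4, where it was 16.6. Covered bases ranged from 5.68 to 17.3 gigabases per library. Without the read length these do not give read counts, so no counting intervals are given.

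Every pair of files was compared before any test. The files labelled F and M at 25 ppb, time point 1, come from a single set of reads: 99.997% of 29846 transcripts above 1 FPKM in both agreed within 0.1%, with a median relative difference of 6.24e-07. In the next closest of the other 119 pairs 0.375% of transcripts agreed this closely. The labels do not settle which line these reads are from, so both files were left out of the comparisons, which rest on 14 libraries. The design fixed before the data were examined had 16, and the values with all 16 are given as an alternative.

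Genes with a mean of at least 1 FPKM over the 14 libraries were tested (31171 genes) on log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), two-sided, with a mean-dependent prior variance and Benjamini-Hochberg adjustment at a threshold of 0.05. A log2 difference on this scale understates the change of genes with low FPKM. The planned fit had the 4 groups of line and ozone level plus time point as a factor, which serves as the block for same-numbered libraries. A number marks a shared collection time by its own label. Libraries of the same time point and line label deviated together in 6 of 6 pairs (correlations across genes of 0.14 to 0.61). Across line labels only 3 of 13 such pairs correlated above 0.1 (-0.52 to 0.29). Deviations were taken from each group's mean over its time points. A line difference that turns around between time points, as found below, therefore adds to these correlations. They do not measure a shared collection effect alone. The time trend was fitted per 30-minute step beside the 4 groups. A further fit, chosen after seeing the data, gave each line label, ozone level and part of the time course (time points 1 and 2, or 3 and 4) its own mean, with 6 residual degrees of freedom. It has no term for single time points. Of its 8 means, 2 rest on a single library (25 ppb at time point 2, labelled F and labelled M). The spread in all fits is that between pooled libraries, so p-values measure only how these libraries vary.

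The tests were checked on simulated data with the real gene means and spreads, in which 200 of 31171 genes were changed. Simulated libraries varied independently, unlike real libraries of the same line label and time point. The shares recovered therefore need not hold for the real data. For the ozone effect averaged over both line labels the planned fit recovered 54% of the genes changed 2-fold and 85% of those changed 4-fold. For the ozone effect averaged over line and part of the time course, the further fit recovered 52% and 88%. For the linear time trend, 93% of genes changing 2-fold per step were recovered.

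Genes are named by a rule fixed before the data were examined: the largest changes either way among genes past the threshold, with a mean of at least 5 FPKM and the same sign in every time-matched pair, the pair condition not applying to the time trend. The planned ozone and line comparisons called no gene, so all genes named for ozone and for the line difference come from the further fit. For comparisons with few calls the rule also asked for the genes with the smallest unadjusted p. Those are not named here. The files give no gene names, and 0 of their 56044 identifiers matched the RefSeq table of assembly Glycine_max_v4.0 used here, so at most 2 identifiers are given each way in a comparison. For the same reason the 39 gene lists fixed beforehand, cell type markers among them, have no members and no gene list test was run. Alternatives covered the pseudocount, the filter, scaling, the prior variance, the choice of transcript, the block and leaving out each library and each time point. Permutation tests and the exact tests used Python 3.11.15 with SciPy 1.17.1.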

Results

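Leaf transcriptomes of 2 soybean lines, labelled F and M, were profiled at 25 ppb ozone and at 75 ppb ozone, at 4 time points within each. The comparisons ask which transcripts respond to elevated ozone, whether the response differs between an ozone-tolerant and an ozone-sensitive line, how the lines differ, and what changes over the sampling period. After the files sharing a single set of reads were set aside, 3 libraries remained in each 25 ppb group and 4 in each 75 ppb group. The first principal component of the 31171 tested genes held 38.6% of the variance and the second 15.7%.

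Many genes differed in the same direction between 75 and 25 ppb ozone in every time-matched pair of libraries. Of 31171 genes, 2624 were higher and 834 were lower at 75 ppb in all 6 pairs. Of the 32 ways of choosing which library of each pair counts as the 75 ppb one, only the real one gave as many genes as these 3458, and the highest other gave 2647. These counts used FPKM as deposited and were not repeated after scaling. The median log2 difference over all genes was 0.17, -0.02 and 0.03 in F at time points 2, 3 and 4. In M it was 0.09, 0.14 and -0.04, so the balance of higher and lower genes may depend on scaling. The planned limma fit called no single gene: 0 passed the adjusted threshold for the ozone effect in F, in M or averaged over both, where the smallest adjusted p-values were 0.607, 0.185 and 0.248. At an unadjusted p under 0.05 there were 2466, 1296 and 3392 genes, against 1559 expected by chance.

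In the fit that also separates time points 1 and 2 from 3 and 4, chosen after seeing the data, 127 genes differed with ozone when averaged over line and time (limma, Benjamini-Hochberg), 111 higher and 16 lower at 75 ppb. Its early 75 ppb means hold time points 1 and 2, and its early 25 ppb means time point 2 only. Ozone is therefore partly mixed with time here. The same holds for the group means below, where only the 75 ppb groups include time point 1. Glyma.06G119600 (chromosome 6, 9735603 to 9735773, a single-exon transcript of 171 bp) rose the most by the naming rule. Its level was 50.03 ± 17.8 FPKM (SD, n = 4) in F at 75 ppb and 10.3 ± 10.6 (n = 3) at 25 ppb, and 43.9 ± 33.2 (n = 4) and 9.64 ± 3.12 (n = 3) in M. The log2 difference was 2.83 ± 0.29 (SE), with an adjusted p of 0.0335 in limma. The same sign in all 6 pairs was a condition of naming. The shared file at 25 ppb, time point 1, entered no test. It stood at 22.4 FPKM, against 74.2 in F and 20.6 in M at 75 ppb, time point 1. With all 16 libraries as labelled the log2 difference was 2.04 (limma adjusted p = 0.0984). FPKM of so short a transcript are imprecise. Glyma.13G319700 (chromosome 13, 41414504 to 41418957, 7 exons) rose by 2.43 ± 0.41 on the log2 scale (limma adjusted p = 0.0479), from 1.19 ± 2.04 (SD, n = 3) to 10.6 ± 6.09 FPKM (n = 4) in F. In M it went from 1.21 ± 0.986 FPKM (n = 3) to 12.6 ± 13.1 (n = 4), with a difference of only 0.07 at time point 2. For this gene the shared file stood at 4.48 FPKM, against 19.1 in F and 2.56 in M at 75 ppb, time point 1. Its call ended in 24 of 27 other settings.

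Glyma.15G107100 (chromosome 15, 8394915 to 8402251, 7 exons) fell by 1.83 ± 0.22 on the log2 scale (limma adjusted p = 0.0335). It stood at 14.9 ± 4.31 FPKM (SD, n = 3) in F at 25 ppb and 2.22 ± 1.05 (n = 4) at 75 ppb, and at 9.66 ± 1.74 (n = 3) and 4.15 ± 4.27 (n = 4) in M. Glyma.07G139700 (chromosome 7, 16580992 to 16582517, 3 exons) fell by 1.81 ± 0.24 (limma adjusted p = 0.0335), from 8.80 ± 5.16 FPKM (n = 3) to 2.48 ± 0.385 (n = 4) in F. In M it went from 11.45 ± 3.26 FPKM (n = 3) to 2.20 ± 1.52 (n = 4). Both were lower at 75 ppb in all 6 pairs, as the naming rule required. The log2 difference was only -0.18 for Glyma.15G107100 in M at time point 2, and only -0.15 for Glyma.07G139700 in F at time point 4. For both, the shared file lay above the F and the M library at 75 ppb, time point 1.

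**Figure D1:**
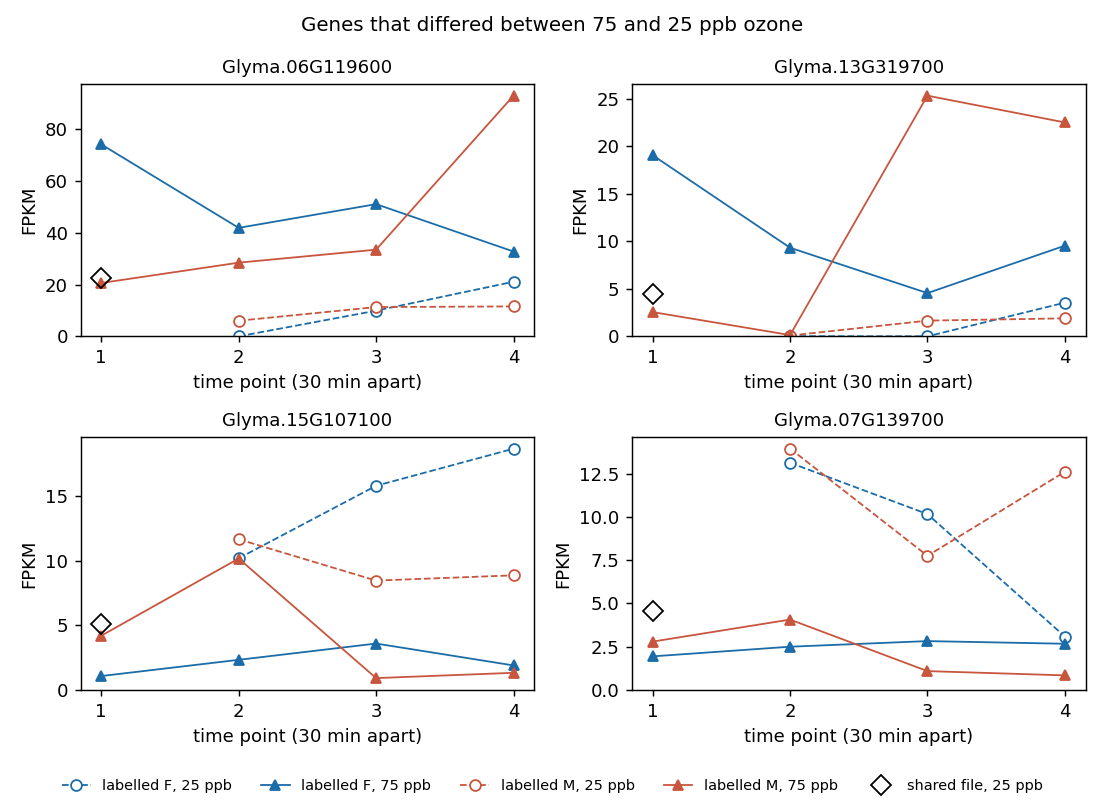
FPKM (vertical axis) of the 4 genes named for ozone at each time point (horizontal axis), 1 library per point, with colour for the line label, filled triangles for 75 ppb and open circles for 25 ppb. The open diamond is the file shared by both lines at 25 ppb, which entered no test. The upper genes were higher and the lower genes lower at 75 ppb in all 6 time-matched pairs, as the naming rule required.

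That fit has no block for line and time. With each pair of line label and time point as a block, 0 of these genes passed (limma, smallest adjusted p = 0.181, with 5623 genes at an unadjusted p under 0.05), while the log2 differences of the 4 named genes were 2.46, 2.24, -1.83 and -1.71. The count of 127 genes also changed with most single libraries, and the log2 differences much less. Leaving out any single library but the 25 ppb ones of time point 2, which that fit needs, gave 2.64 to 3.01 for Glyma.06G119600, 2.16 to 2.71 for Glyma.13G319700, -1.97 to -1.70 for Glyma.15G107100 and -1.99 to -1.63 for Glyma.07G139700. The count was 0 without time point 1, 3 or 4, without F at 75 ppb at time points 1, 2 or 3, without M at 75 ppb, time point 2, and without M at 25 ppb, time point 4. It was 1 without M at 25 ppb, time point 3 or F at 75 ppb, time point 4, 11 without M at 75 ppb, time point 1 and 46 without F at 25 ppb, time point 3. It was 254 without M at 75 ppb, time point 3, 609 without F at 25 ppb, time point 4 and 588 without M at 75 ppb, time point 4. The balance of directions depended on scaling and on the filter: 87.4% of the calls were higher at 75 ppb as deposited, 61.1% of 36 after median-of-ratios scaling and 52% of 25 after quantile normalization. Without the filter on low values 106 genes were called, 52 higher and 54 lower. Of the 127, 3 genes had no residual spread because nearly all their signal lay in a library that alone makes up its mean.

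The ozone difference varied in size among the 6 pairs of libraries. More than 2-fold differences were seen for 4224 genes in F at time point 2, 3206 at time point 3 and 1019 at time point 4. In M they were seen for 1050 genes at time point 2, 4954 at time point 3 and 5058 at time point 4. Each pair is a single library against a single library, so these counts have no replicate check. Across genes, which are not independent replicates, the 15 correlations between pairs ranged from -0.04 to 0.52. Within F they were 0.42, 0.31 and 0.23, and within M 0.19, -0.01 and 0.27. Between the labels the highest were 0.52 (F at time point 2 with M at time point 4), 0.36 (F at time point 3 with M at time point 4) and 0.35 (F and M at time point 3). F at time point 2 with M at time point 3 gave 0.21, and M at time point 2 gave -0.04 to -0.03 with the 3 pairs of F.

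**Figure D2:**
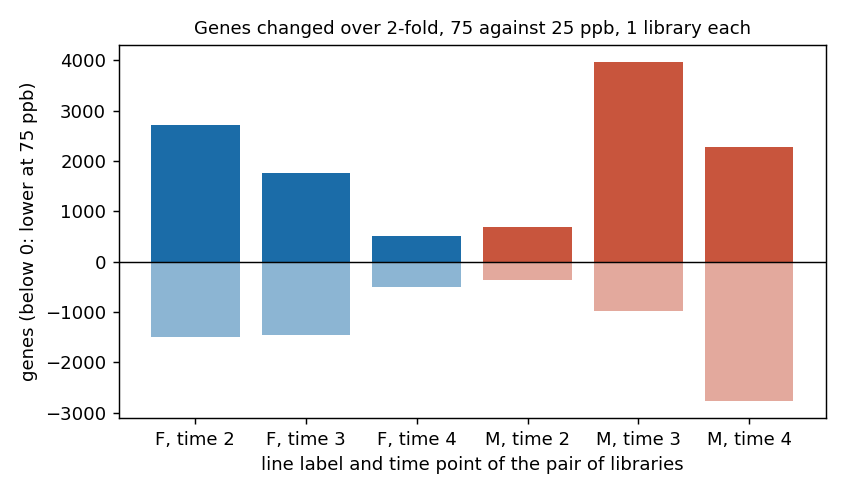
Number of genes (vertical axis) that differed more than 2-fold between the 75 and 25 ppb libraries of each line label and time point (horizontal axis), with genes higher at 75 ppb above 0 and genes lower at 75 ppb below 0. The fewest genes, 1019 and 1050, were in F at time point 4 and in M at time point 2.

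The ozone response was not found to differ between the line labels. No gene passed in the planned limma fit (597 at an unadjusted p under 0.05) and none in the fit that separates the parts of the time course (623 genes). For a single line label at time points 3 and 4, that fit called 20 genes in M, 18 of them higher at 75 ppb, and 1 in F. At time points 1 and 2 it called 5 in F and 2 in M, but these rest on a single 25 ppb library per label, and 2 of the 5 and 1 of the 2 had no residual spread. Within each part F and M had equal numbers of libraries and the same median SE (0.398 early, 0.325 late), but the test of the difference between them called 0 genes at time points 1 and 2 (1365 at an unadjusted p under 0.05) and 0 at time points 3 and 4 (857 genes). Averaged over the parts, 3 genes were called in F, 2 of them without residual spread, and 1 in M. In simulated data with independent libraries the planned fit recovered 42% of genes whose ozone effect differed 4-fold between lines. It recovered 1% of those that differed 2-fold, so a 2-fold difference was rarely detectable even there.

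The lines differed strongly, but the direction belonging to each label turned around between time points 2 and 3. Glyma.19G169800 (chromosome 19, 43050652 to 43055928, 6 exons) had 24.3 to 33.4 FPKM in the 3 libraries labelled M at time points 1 and 2, and at most 0.03 in the 3 labelled F. At time points 3 and 4 it was listed at 0 in all 4 libraries labelled M and reached 36.9 FPKM in those labelled F. Glyma.16G151000 (chromosome 16, 31148829 to 31151842, 4 exons) had the same pattern, with 22.7 to 39.5 FPKM in M and 0 in F early, and at most 0.05 in M late. Glyma.05G098600 (chromosome 5, 26207237 to 26209499, 3 exons) went the other way, with 53.2 to 97.8 FPKM in F early, at most 0.4 in M early, 38.15 to 61.9 in M late and at most 0.28 in F late. Glyma.04G105900 (chromosome 4, 10789400 to 10791837, 2 exons) changed in the same direction as Glyma.05G098600. The limma test of the difference between the parts of the time course gave adjusted p-values of 4.93e-07, 5.59e-07, 4.93e-07 and 7.45e-07 for these 4 genes. A sign that held in all 7 pairs of libraries was a condition of naming them.

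**Figure D3:**
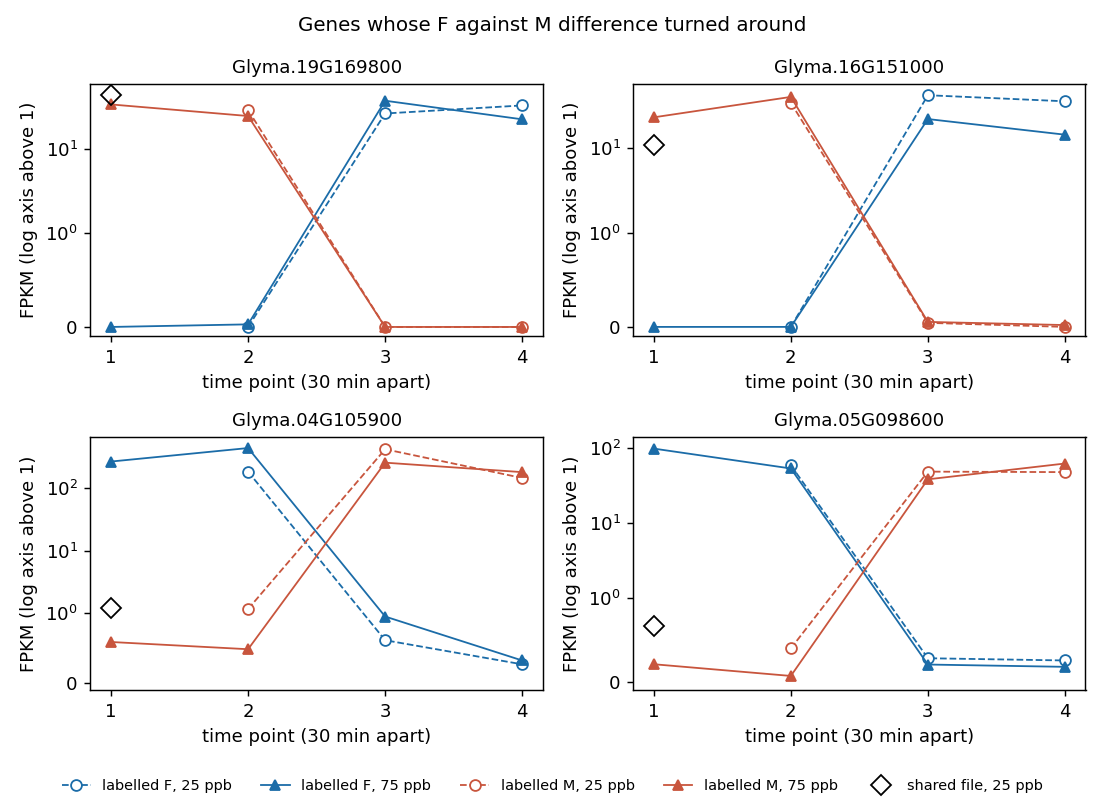
FPKM (vertical axis, logarithmic above 1) of 4 genes at each time point (horizontal axis), 1 library per point, with colour for the line label, filled triangles for 75 ppb, open circles for 25 ppb and an open diamond for the file shared by both labels. Each gene is high under one label at time points 1 and 2 and under the other label at time points 3 and 4.

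Across all genes the pooled comparisons of F with M called 0 genes at 25 ppb (295 at an unadjusted p under 0.05, limma) and 0 at 75 ppb (512 genes). Within time points 1 and 2, in the fit chosen after seeing the data, 321 genes differed, 132 higher in F and 189 lower. That count was 235 to 558 without a single library, 135 without time point 3 and 132 without time point 4. The 25 ppb libraries of time point 2 could not be left out. Within time points 3 and 4, 652 genes differed, 333 higher and 319 lower, but the count was 297 to 861 without a single library, 68 without time point 3 and 85 without time point 4. Of these 652, 287 were called in both parts, and all 287 had opposite signs, where independent lists would share 3.4 genes of opposite sign. The difference between the parts was itself significant for 1611 genes (868 to 2379 without a single library, 374 without time point 3 and 575 without time point 4), and across genes the 2 log2 differences correlated at r = -0.78. Line differences of single pairs of libraries correlated at 0.17 to 0.49 within a part of the time course (9 comparisons) and at -0.78 to -0.24 between the parts (12 comparisons). The count for time points 1 and 2 was 0 with all 16 libraries as labelled, 4 with the shared file under F only and 399 with it under M only.

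A set of 11 genes had at least 10 FPKM in 7 libraries and under 0.5 FPKM in the other 7, along the crossed pattern: 5 were on in F early and M late, 6 in M early and F late. With the same limits 0 genes followed the F or M label through all time points, and 0 followed the ozone level. Of the 64 ways of dividing the 7 pairs of libraries, only the crossed one held such genes. A line score, the mean log2(FPKM + 1) of genes higher in F minus that of genes higher in M, was taken from genes called in a separate limma fit of the 8 libraries of time points 3 and 4 alone, with line label and ozone level as terms (441 genes higher and 317 lower in F). This score lay between -1.79 and -0.92 in the 3 libraries labelled F at time points 1 and 2, and between 1.39 and 2.43 in the 3 labelled M. The same fit of the 6 libraries of time points 1 and 2 gave 96 and 144 genes, which scored the later libraries at -2.84 to -1.80 for F (n = 4) and at 2.39 to 2.63 for M (n = 4). All statements on line-specific ozone effects above depend on these labels.

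**Figure D4:**
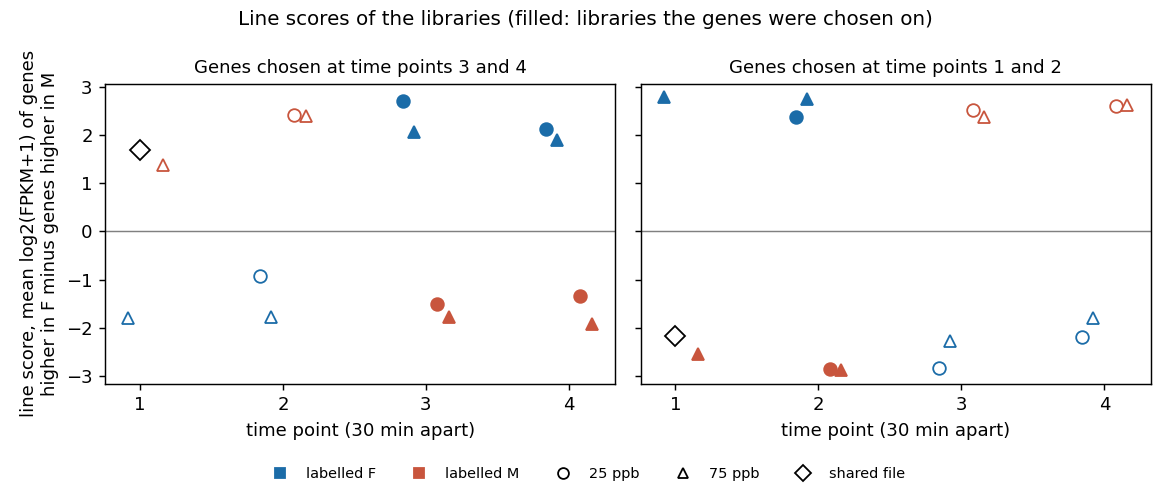
Line score (vertical axis, log2 units) of each library by time point (horizontal axis), with colour for the line label, circles for 25 ppb, triangles for 75 ppb, filled symbols for libraries on which the genes were chosen and an open diamond for the file shared by both labels. Apart from the shared file, libraries not used to choose the genes lie on the side opposite to their label. In the left panel they lie at -1.79 to -0.92 for F and 1.39 to 2.43 for M, and the shared file at 1.70.

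Over the sampling period, 258 genes had a linear trend across the 4 time points (limma), 62 rising and 196 falling. The fit treats libraries of the same line label and time point as independent, although they deviated together. With such libraries kept together, 13 of 100 random orderings of the time points, drawn separately in F and M, called at least 258 genes. The highest other called 2821. Such orderings can turn the crossed line difference into a time trend, so this share cannot decide on chance. With both lines reordered together the highest other order called 0 genes, but 12 orders are too few for a share under 0.05. Chance was therefore not excluded. Glyma.08G334500 (chromosome 8, 45193906 to 45196355) rose by 1.72 ± 0.30 (SE) on the log2 scale per 30-minute step (limma adjusted p = 0.0292), and Glyma.18G067500 (chromosome 18, 6269068 to 6271310) by 1.43 ± 0.21 (limma adjusted p = 0.0152). Glyma.11G158200 (chromosome 11, 14138769 to 14142925) fell by 1.04 ± 0.12 per step and Glyma.06G125700 (chromosome 6, 10255309 to 10258885) by 1.02 ± 0.13, both with a limma adjusted p of 0.00651. With the highest transcript in place of the sum, Glyma.11G158200 fell by 0.42 per step (limma adjusted p = 0.639). Over 30 settings the 4 genes kept their sign and passed in 19, 21, 24 and 24, with adjusted p-values from 0.000423 to 0.639. A difference of the trend between ozone levels was called for 0 genes (236 at an unadjusted p under 0.05, limma), and for 1 without the filter or without M at 25 ppb, time point 2. In simulated data with independent libraries 24% of 2-fold differences per step were recovered, so most of that size were not detectable even there.

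No gene was called when time point 4 was set against time point 1, or when any single time point was left out. The count was 14 without F at 75 ppb, time point 4, 29 without M at 75 ppb, time point 1, 54 and 57 without M at 75 and 25 ppb, time point 4, and between 120 and 341 without any other library. It was 448 after median-of-ratios scaling (75 rising and 373 falling) and 1527 with all 16 libraries as labelled. With all 16, 834 genes rose and 693 fell, so the excess of falling genes was not kept there. That fit counts the shared reads as 2 separate libraries. With the shared file under a single label the excess was kept. Under F only, 186 genes rose and 313 fell, and under M only, 323 rose and 465 fell.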

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

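All tests in this part were chosen after the results they bear on had been seen; the 8 planned comparisons were fixed before.

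The difference between F and M differed between time points 1 and 2 and time points 3 and 4, by a test of that difference, for 1611 genes. Of 64 exchanges of F and M within pairs of libraries only the real arrangement, 1 of 64, gave as many, and the highest other gave 238. The arrangement was noticed in these libraries before it was counted, so this share alone does not exclude chance. For the separate counts of 321 and 652 genes, the 4 and 8 exchanges possible are too few for a share under 0.05, and 1 arrangement, the real one, reached each count, with 0 genes in the highest other. A depth difference between the lines is argued against, since the F library was the shallower one in 7 of 7 pairs, before and after it. A candidate explanation is that the line labels were exchanged in one part of the time course. With the shared file left out, genes of time points 3 and 4 put 6 of 6 libraries of time points 1 and 2 on the side opposite to their label. A line-specific change of expression with time would also give opposite changes from early to late in F and M (r = -0.59 across genes), so that correlation cannot separate them. Such a change would have to reverse nearly all called line differences. Of the 652 genes called late 650 had the opposite sign early, and of the 321 called early 319 had the opposite sign late. Of 287 genes called in both parts, 0 kept their sign. Averaged over the parts, F against M called 0 genes (limma, 269 at an unadjusted p under 0.05). These values argue against a line-specific change for the called genes. They do not exclude it, since each line was sampled once per time and ozone level. No label was changed here.

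The size of the ozone difference varied between the pairs of line and time. Noise from low depth stays open: over the 6 pairs the spread of log2 differences had a rank correlation of 0.14 with the depth of the shallower library (two-sided exact permutation p = 0.803) and a Pearson r of 0.28 (p = 0.594). The deepest pair (M at time point 4) had the largest spread and the next deepest (M at time point 2) the smallest. Without the deepest pair the rank correlation was -0.50, and without the 2 pairs farthest from the median depth r was -0.29. The spreads followed the same crossing of the line labels: F at time point 2 and M at time points 3 and 4 had SDs of 0.75, 0.85 and 0.88, and the other pairs 0.67, 0.47 and 0.44. The two-sided exact permutation p was 0.1, the smallest that 3 pairs against 3 can give, so a larger response in one line, read through crossed labels, cannot be told apart from chance, from noise or from a response that differs with time in each line. The test of line by part of the time course by ozone called 0 genes (limma, 1812 at an unadjusted p under 0.05).

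The share of covered bases at annotated genes was 86.2% in F at 75 ppb, time point 2, and 93.5% in the nearest of the other 3 libraries of its group, a gap of 0.911 of the range of the group and above the 95% limit of Dixon's test. It was the only library measure or named gene so placed among 32 groups of 4 libraries tested, where chance gives 1.6.

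For the ozone effect averaged over line and part of the time course, 1 of 64 exchanges within ozone pairs, the real one, reached 127 genes, and the highest other called 102. Taking the highest count of the 3 fits tried in each exchange gave the same 1 of 64, with 102 in the highest other. The fit was chosen after the planned one had called 0 and the line-by-time block calls 0, so chance stays open for this count. For the linear time trend 2 of 100 orderings of time within groups reached 258 genes, and another called 674, but these orderings separate libraries of the same line and time, which deviate together. With such libraries kept together, 13 of 100 orderings drawn separately in F and M reached 258, and the highest other called 2821. These orderings can turn the crossed line difference into a time trend, so the share cannot decide on chance. With all libraries of a time kept together, 12 orders are too few for a share under 0.05; 1, the real one, reached 258, and the highest other called 0. For the planned comparisons that called no gene, splits were compared by genes at an unadjusted p under 0.05. As many genes came from 6 of 35 splits for ozone in F (2466, highest other 7700), 19 of 35 for ozone in M (1296, highest other 7840) and 19 of 100 for the average (3392, highest other 9151), so chance could not be excluded by these, but they too separate libraries of the same line and time. With such pairs kept and 75 and 25 ppb exchanged within them, in the fit with the line-by-time block, 1 of 32 exchanges, the real one, gave 5623 genes for the average, and the highest other 4733. The lowest share these exchanges can give is 1 of 32, and they were added after the splits above had been seen. They argue only weakly against chance for the averaged ozone difference over all genes, and not for any single gene. Within a line the 4 exchanges are too few for a share under 0.05; 1, the real one, reached 3304 genes in F (highest other 741) and 1 reached 3522 in M (highest other 2271). For the remaining comparisons with enough splits chance could not be excluded. As many genes came from 66 of 100 splits for the difference between lines (597, highest other 6757). For F against M at 75 ppb they came from 27 of 35 splits (512, highest other 6968), and for the time trend by ozone from 93 of 100 (236, highest other 5340). For F against M at 25 ppb the 10 splits are too few for a share under 0.05; 9 reached the real count of 295, and the highest other was 3019. Splits with several times the real count point to a structure of the libraries that the line and ozone labels do not follow.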

How the results depend on the processing

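The pseudocount, filter, scaling, prior variance, transcript, block and leave-one-out settings of the planned comparisons were chosen before the data were examined; the 16-library fits, the shared file under a single label, annotated transcripts only, the line-by-time block, the fits by part of the time course and all settings of the fits that separate its parts were added after seeing the data. The cause of the changes below was not tested unless stated.

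For ozone in F no setting of the planned fit called a gene. For ozone in M, 2 genes were called with a pseudocount of 0.1, 2 at time points 1 and 2 only and 2 at time points 3 and 4 only. For the average, 1 was called without the filter, 1 with all 16 libraries, 1 with the shared file under M and 1 at time points 1 and 2 only. For the difference between lines 1 was called at time points 1 and 2 only, and for the time trend by ozone 1 without the filter. Leaving out any library or time point gave 0 for the ozone and line comparisons of the plan, and 0 to 1 for the time trend by ozone. Leaving out the replicate block (time) gave 0 for all 6 planned ozone and line comparisons, and a line-by-time block gave 0 for the 4 ozone ones, so neither changed a call of the plan. The line-by-time block took the averaged ozone effect of the added fit from 127 to 0. F against M at 25 ppb gave 1 with a pseudocount of 0.1 and 224 at time points 3 and 4 only. At 75 ppb it gave 213 at time points 1 and 2 only and 186 at 3 and 4 only.

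The time trend (258) became 141 without the filter, 448 with median-of-ratios scaling, 76 with the highest transcript, 126 with annotated transcripts, 1527 with 16 libraries, 499 or 788 with the shared file under F or M, 0 for time point 4 against 1, and 0 to 341 leaving out libraries or time points. The averaged ozone effect (127) became 37 at a mean FPKM of 5 or more (fewer genes tested), 36 with median-of-ratios scaling, 25 with quantile normalization, 7 with the highest transcript, 69 with annotated transcripts, 399 with 16 libraries, 269 with the shared file under M, and 0 to 609 leaving out libraries or time points. Of the 36 and 25, 34 and 25 were among the 127.

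F against M at time points 1 and 2 (321) became 513 without the filter, 132 at a mean of 5 or more, 168 with the highest transcript, 170 with annotated transcripts, 0 with 16 libraries and 4 with the shared file under F. It was 132 to 558 leaving out libraries or time points. At time points 3 and 4 (652) it became 255, 307 and 307 for the filter at 5, the highest transcript and annotated transcripts, 422 with the shared file under F, and 68 to 861 leaving out libraries or time points. The difference between the parts (1611) became 717, 836 and 855 for the same 3 settings and 374 to 2379 leaving out libraries or time points. No named gene changed sign in any setting. The 4 genes named for the line difference passed in all 26 settings each, the 4 named for ozone in 14, 3, 14 and 13 of 27, and the 4 named for time in 19, 21, 24 and 24 of 30.

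Without F or M at 25 ppb, time point 2, the fits that separate the parts lose a mean, so the averaged ozone effect, F against M at time points 1 and 2 and the difference between the parts have no value there. The time trend by ozone for time point 4 against 1 could not be estimated without a 25 ppb library at time point 1, and the gene list tests were not run. FPKM without read counts leaves the counting error of low genes unknown.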

Other observations

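The tests in this part were chosen after the results had been seen. Genes whose F against M difference differed between the parts of the time course, by the test of that difference, lay close together on the chromosomes. Among the 1611, 192 pairs were direct neighbours among tested genes, against a mean of 83.4 in 2000 random sets matched on mean FPKM (permutation p = 0.0005, the smallest these sets can give, adjusted 0.0025 over 15 tests). Chromosome 16 held 109 of them where 59.5 were expected (Fisher's exact adjusted p = 1.02e-07 over 100 tests), chromosome 18 held 108 where 78.8 were expected (adjusted p = 0.0435), and chromosome 9 held 53 where 78.4 were expected (adjusted p = 0.0484). They had a median length of 1634 bp against 1784 bp in the random sets (permutation adjusted p = 0.00375), and 14.5% had a single exon against 12% of the other tested genes (Fisher's exact adjusted p = 0.00861). The longest run had 6 neighbouring genes on chromosome 18, from 55425250 to 55469198. Fisher's test treats genes as independent, while these genes lay close together, so its p-values may be too small. This matters most for chromosomes 18 and 9, whose values were near the threshold.

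The sets of 111 and 16 genes come from the fit chosen after seeing the data; a line-by-time block called 0 of them, rescaling gave 22 higher and 14 lower genes or 13 and 12, and 3 of the 127 had no residual spread. With this limit, the genes called for ozone had more single-exon members than the other tested genes: 21.6% of the 111 higher genes (Fisher's exact adjusted p = 0.0123) and 50% of the 16 lower genes (adjusted p = 0.0018), against 12.1%. The 16 lower genes had a median length of 868 bp, against 1764 bp in 10000 random sets matched on mean FPKM (permutation adjusted p = 0.0018). Of the genes higher at 75 ppb, 12 lay on chromosome 14 where 4.3 were expected (Fisher's exact adjusted p = 0.0456). Of the 196 genes falling with time 18.9% had a single exon (Fisher's exact adjusted p = 0.0124) and of the 62 rising 4.8% (adjusted p = 0.134). Chance was not excluded for these lists, since neither ordering test that kept libraries of the same line and time together could decide it.

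The share of a library's gene FPKM in newly assembled transcripts was higher at 75 ppb in 6 of 6 pairs, by a mean of 0.727 percentage points. The two-sided exact permutation p was 0.0312, the smallest that 6 pairs allow, and 0.125 after adjustment over 4 library measures. The shared file at 25 ppb, time point 1, is in none of these pairs. Its share of 11.4% was above those at 75 ppb, time point 1 (11.17% in F and 9.23% in M). The shares were not adjusted for depth. Covered bases, the share at annotated genes and the number of transcripts away from annotated genes differed with exact adjusted p-values of 0.251, 0.812 and 0.251.

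The single set of reads under the F and the M label at 25 ppb, time point 1, scored 1.70 with genes of time points 3 and 4 and -2.17 with genes of time points 1 and 2. The 3 other libraries labelled M at time points 1 and 2 scored 1.39 to 2.43 on the first score and the 3 labelled F scored -1.79 to -0.92. On the second score these 3 libraries labelled M, on which its genes were chosen, scored -2.88 to -2.55. The 4 libraries labelled F at time points 3 and 4, not used to choose its genes, scored -2.84 to -1.80. The values argue against reads from the material of the library labelled F at 75 ppb, time point 1, and a candidate explanation is that the reads belong with the early libraries labelled M. In the shared file Glyma.19G169800 stood at 42.9 FPKM.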
